A study of Drosophila melanogaster with 6 samples.

How the data were processed

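RNA was measured in 6 samples of Drosophila melanogaster, 3 labelled GFP control and 3 labelled InR-DN, each from 200 embryos of 16 to 20 h. Per the labels' protocols, RNA was isolated with TriPure reagent and libraries were made with an Illumina TruSeq stranded total RNA kit, while the sample descriptions say that polyadenylated RNA was selected. Per the submitters' processing notes, FastQC, Bowtie and TopHat were used; their versions are not given in the sources used here. The read counter, the genome build, the filters and whether strand was used in counting are not given in the sources used here either, so overlapping and antisense genes cannot be told apart with certainty and no coordinates are given.

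The file analysed is the authors' deposited table of the comparison, with 1 row per gene for 14862 genes. Per the file headers it is a results table of edgeR's likelihood ratio test (glmLRT). The authors' log2 fold change is the fitted difference between the compared groups, with the numerator not stated. The deposited average log2 CPM is a mean over all libraries of the authors' fit, shrunk by a prior count. The authors' likelihood ratio statistic is a score with 1 degree of freedom, and the deposited p-value is its chi-square tail, with a largest difference of 6.38e-15 when recomputed. The authors' adjusted p-value is the Benjamini-Hochberg value over the rows, recomputed with a largest difference of 3.55e-15. No column holds a value per sample, and 0 columns belong to other samples.

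The design set before the data were examined was a count test on values per sample. As the table holds none, the planned fallback was used: the authors' fold changes and adjusted p-values as deposited, with no refit and a threshold of 0.05. An implied SE was computed per gene as the size of the log2 fold change over the square root of the likelihood ratio statistic, which treats the test as a Wald test. No standard deviation, value per replicate or check of replicates against each other could be made. Gene names were matched to the reference annotation of Release 6 by symbol or synonym for 14707 genes (98.96%), for names only. Among genes above a log2 average of -1, 190 genes in 84 groups have the same average log2 CPM rounded to 6 decimals and the same log2 fold change rounded to 4 decimals, which points to shared reads, and 9 of them were called.

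Library number and size were computed from the average log2 CPM. Genes with 1 read in 1 library take 1 level per library, and the effective sizes were solved from these levels with a prior count of 2 and 1 dispersion, estimated at 0.0533. As a check, 76 of the 78 levels predicted for genes with 2 reads were found in the table within 1e-05. The side of a library is the sign of the fold change of its single-read genes. The recovered sizes average 29.0 and sum to 347, in units of 1000000 reads, over 12 libraries. On 1078 simulated genes the step recovered 12 of 12 libraries. The highest CPM that the compared libraries can hold assigns every read of the fit to them, with at least 3 reads, except for genes with no read in them, which are set at the limit of 3 reads. The lowest number of reads per library is the number at which counting noise alone would give the implied SE. For genes whose low side held 3 reads or fewer over its 3 libraries, the fitted fold depends on the prior count of 0.125. Where the low side held under 1 read, such genes are given as N-fold the level of 3 reads over the group. Otherwise no fold is given. The N-fold is a lower limit where the prior count set the level. It is an upper limit where giving every read of the fit to the high side set the level.

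Gene lists, 44 in number and fixed before the data were examined, were tested with cameraPR (limma 3.58.1 in R 4.3.3) on the signed square root of the likelihood ratio statistic, with a preset inter-gene correlation of 0.01 and at least 5 members, adjusted over the 43 lists tested. An estimated correlation needs values per library and was not analysed here. On simulated statistics for 14862 genes, cameraPR recovered 11.5% of lists of 20 genes shifted by 0.5, 96.5% of those shifted by 1 and 100% of those shifted by 2, and 3.26% of unshifted lists had a p under 0.05. The simulated statistics were normal and independent between genes, so these rates do not cover lists whose members vary together.

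The genes named were chosen by a rule set before the data were examined. It takes InR; among genes with an adjusted p under 0.05 and an average log2 CPM of 0 or more, the 10 largest changes per side and the 4 smallest p-values per side with a symbol other than a CG or CR number; and up to 3 members per list with the smallest unadjusted p. Adh, Rfabg, Osi19, Tm1 and unc-13 in the report, and the tissue markers and abundant genes of the closing section, were named after their values were seen. The alternatives were an adjusted p under 0.01, a 2-fold minimum, a minimum average of 1 CPM, and for the lists a rank-based test, a correlation of 0.05 and the log2 fold change as the statistic. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 did the rest.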

Results

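The series asked which embryonic genes differ when insulin signalling is lowered in the maternal germ line of Drosophila melanogaster. The 6 samples fall into 2 groups of 3. In 1 group the oocytes expressed a dominant-negative insulin receptor (InR-DN), a receptor form that blocks signalling by the normal protein, and in the other they expressed green fluorescent protein (GFP) as the control. Each sample is RNA from 200 embryos labelled as 16 to 20 h old. The labels do not say whether the 3 samples of a group came from separate crosses, so the spread behind the p-values may be technical; it is that of the authors' fit, which held more libraries than these samples. The values used are those of the authors' deposited table of this comparison, which holds 14862 genes with a log2 fold change, an average log2 CPM, a likelihood ratio statistic and p-values, and no value per sample. Which group is the numerator is not given in the sources used here and could not be settled from the values, so genes are placed on the positive or the negative side of the deposited fold change and no gene is said to be higher in InR-DN or in GFP.

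The depth was read from genes with a single read. In the authors' deposited table such genes take 12 distinct average levels, so 12 libraries entered the fit, of which 3 set the positive side, 3 set the negative side and 6 had no part in the fold change. The effective library sizes computed from these levels were, in units of 1000000 reads, 25.7, 37.3 and 40.5 on the positive side and 23.4, 29.6 and 31.1 on the negative side. The other 6 ranged from 15.8 to 33.0 in that unit. A gene with no read in the 6 compared libraries could still reach 0.0160 CPM over them, the level that 3 reads would give. This limit covers counting error only.

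Digestive enzymes were prominent on the positive side, where 20 of 29 midgut proteases changed in the authors' deposited table. On the negative side the genes with the largest deposited fold changes at 1 CPM or more included CG42704, CG43090, the antifungal peptide gene Drosomycin (Drs) and Shawl. No gene of the lists for insulin signalling, respiration, cytosolic ribosomes or Polycomb and Trithorax proteins passed the edgeR threshold. The authors' deposited table calls 667 of 14862 genes (4.49%) at a Benjamini-Hochberg adjusted p under 0.05 from the edgeR likelihood ratio test, 342 on the positive and 325 on the negative side. Of these calls in the authors' deposited table, 309 had an average below 1 CPM, 270 an average of 1 to 16 CPM, and 88 an average of 16 CPM or more. These 88 genes were 1.38% of the 6398 genes at that level, and 51 of them differed by 2-fold or more in the authors' deposited table. Every average is over the 12 libraries of the fit, 6 of them not compared. A gene with a high average can thus be scarce in the compared libraries, and slp2, at an average of 58.0 CPM, had no read there. Among genes with an average of 1 CPM or more, 220 called genes lay on the positive side and 138 on the negative side.

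**Figure D1:**
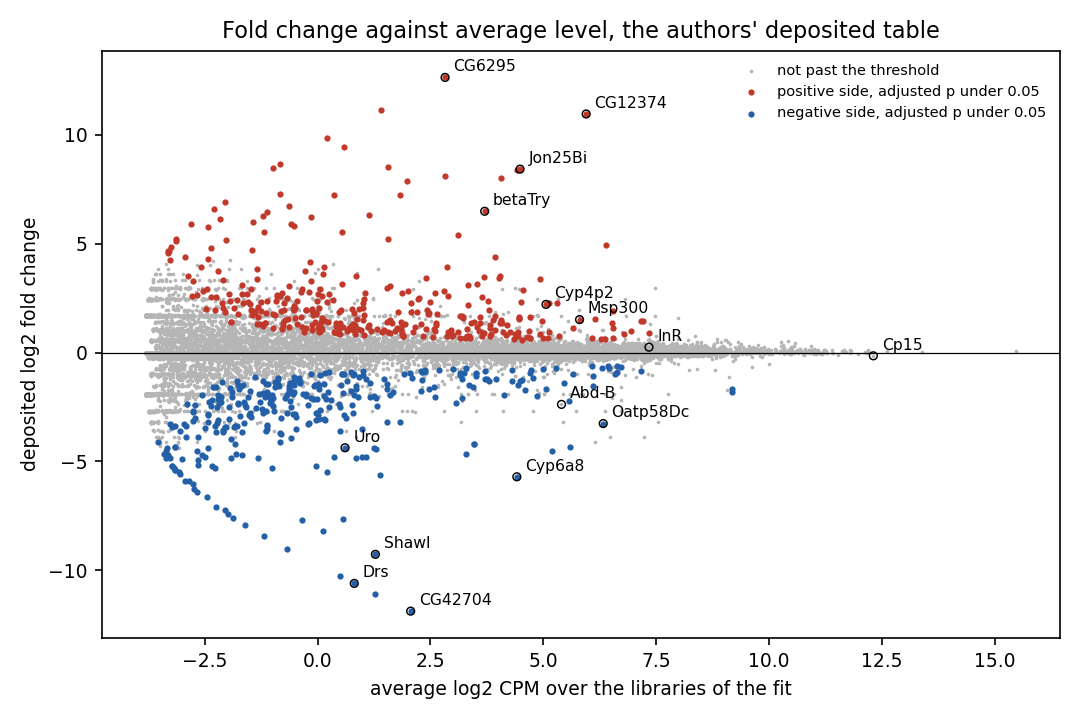
Deposited log2 fold change (vertical axis) against the average log2 CPM over the libraries of the fit (horizontal axis) for the genes of the authors' deposited table, 1 point per gene. Red and blue points are the 342 positive and 325 negative genes with an adjusted p under 0.05, 309 of them below 1 CPM; circles mark 15 named genes, among them InR at 0.25.

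InR, the receptor whose dominant-negative form the transgene encodes, had a log2 fold change of 0.25 (implied SE 0.26) at an average of 162 CPM in the authors' deposited table, with an adjusted p of 1 in the edgeR test. It therefore does not tell the 2 groups apart, and whether reads of the transgene would count to InR is not given in the sources used here. None of the 19 insulin and TOR pathway genes, 6 insulin-like peptides and 7 genes that the transcription factor foxo is known to induce passed the edgeR threshold (0 of 29 different genes), over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there was 1, the insulin-like peptide gene Ilp7, with a log2 fold change of 0.61 (implied SE 0.26) in the authors' deposited table. ImpL2, a secreted binding protein of insulin-like peptides, had 0.31 (implied SE 0.22) and Thor, the translation repressor 4E-BP, had 0.20 (implied SE 0.20) in the authors' deposited table.

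Secreted proteases of the midgut formed the clearest group. In the authors' deposited table, 20 of 29 changed on the positive side, 2 on the negative side and 7 did not pass the edgeR threshold, and adjusted over the list alone the counts were 21 and 3. Trypsin-like and Jonah proteases led with log2 fold changes in the authors' deposited table of 8.43 for Jon25Bi (implied SE 0.36), 8.01 for Jon25Bii (implied SE 0.37), 8.12 for Jon99Ci (implied SE 0.43) and 6.49 for betaTry (implied SE 0.33), each with an average of 22.4 CPM or less. The median of the 29 genes was 1.56 on the log2 scale in the authors' deposited table, and cameraPR, limma's competitive test of a list against all other genes, gave an adjusted p of 9.95e-103. With ranks in place of the statistic, the cameraPR adjusted p was 8.41e-04. Several of these genes are close paralogs, so reads may be split between them.

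Carbohydrate digestion, the maltases and amylases, went the same way, with 6 of 14 changed on the positive side and 0 on the negative side in the authors' deposited table, over all genes and adjusted over the list alone. Mal-A6 had a log2 fold change of 5.22 (implied SE 0.37), Mal-A7 of 5.82 (implied SE 0.51) and Amy-d of 3.44 (implied SE 0.34) in the authors' deposited table. For Mal-A7 the negative side held at most 3.11 reads, so its fold may depend on the prior count. The cameraPR adjusted p was 1.32e-17, and 0.176 when ranks replaced the statistic. Among the 10 largest positive changes at 1 CPM or more, the carboxypeptidase-like gene CG12374 had 10.96 (implied SE 0.41, average 61.7 CPM) and CG30272 had 8.37 (implied SE 0.77) in the authors' deposited table. For CG6295, CG17192, CG3819 and CG31219 the negative side held under 1 read over its 3 libraries. CG6295, CG17192 and CG3819 could reach at most 661-fold, 244-fold and 102-fold the level of 3 reads on the positive side. These limits give that side every read of the fit. CG31219 was at least 84.0-fold the level of 3 reads there. For LysB, a lysozyme gene of the midgut, the negative side held at most 2.18 reads, and no fold is given.

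Products of larval fat body and muscle lay on the positive side as lists. The storage protein genes Lsp2 (3.73, implied SE 0.39) and Lsp1beta (2.71, implied SE 0.63) were the 2 changed genes among 8 of the fat body list in the authors' deposited table, both below 1 CPM, while the abundant members Adh (-0.14) and Rfabg (0.14) did not pass the threshold. The list's cameraPR adjusted p was 2.96e-03, and 0.105 by ranks. Its median of 1.58 in the authors' deposited table falls to 0.07 when the 2 members at or under 3 reads on a side are set at their bound. Among 18 contractile protein genes 1 changed, Msp300, a giant actin-binding protein of muscle nuclei, with 1.51 (implied SE 0.21) at 55.8 CPM in the authors' deposited table; adjusted over the list alone there were 2. The muscle list had a cameraPR adjusted p of 1.26e-03, and 0.267 with the log2 fold change as the statistic. The digestive lists lay on the same side, and whether a differing share of tissue accounts for the fat body and muscle lists was not tested.

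Antimicrobial defence changed on the negative side. In the authors' deposited table, 5 of 27 peptide and recognition genes passed on that side and 0 on the other, and 8 adjusted over the list alone, with a cameraPR adjusted p of 2.19e-05. Drs, an antifungal peptide, had under 1 read over the positive-side libraries and at least 233-fold the level of 3 reads on the negative side. The diptericin genes Dpt and DptB had log2 fold changes of -3.36 (implied SE 0.69) and -2.45 (implied SE 0.62) in the authors' deposited table, at averages of 0.291 and 0.195 CPM. Most members were scarce: 6 of the 27 averaged 1 CPM or more in the authors' deposited table, and the median fold of -0.48 becomes -0.10 with the 8 floor-level members at their bound. Genes of the Malpighian tubules (13 of 21) and spermathecae (8 of 9) also changed on the negative side, and 0 on the positive side. Those lists were gathered after the called genes were seen. Whether a differing share of tissue accounts for the antimicrobial genes was not tested.

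Other genes with large negative changes were of several kinds, and no list was tested for them as a set. Cyp6a8, a cytochrome P450, had -5.71 (implied SE 0.59) at 21.3 CPM, Uro, the urate oxidase of the Malpighian tubules, had -4.38 (implied SE 0.35), and Oatp58Dc, an organic anion transporter, had -3.26 (implied SE 0.34) at 80.2 CPM in the authors' deposited table. CG14499 had -5.63 (implied SE 0.38), CG13728 had -5.48 (implied SE 1.13) and the odorant-binding protein gene Obp56a had -7.63 (implied SE 1.17) in the authors' deposited table. For Obp56a the positive side held at most 3.06 reads, so its fold may depend on the prior count. For CG42704, CG43090 and CG42705 the positive side held under 1 read over its 3 libraries and the negative side at least 563-fold, 322-fold and 186-fold the level of 3 reads. The potassium channel gene Shawl had at most 1.63 reads on the positive side and the serine protease gene CG31681 at most 1.50, and no fold is given.

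Cytochrome P450 genes changed in both directions, with 8 of 61 on the positive side and 7 on the negative side in the authors' deposited table (8 and 8 adjusted over the list alone; cameraPR adjusted p 0.517). Cyp4p2 had 2.21 (implied SE 0.22) at 33.3 CPM against -2.14 (implied SE 0.29) for Cyp6w1 in the authors' deposited table. Among 38 glutathione genes, the transferases GstE10 (-1.44, implied SE 0.25) and GstT1 (-0.62, implied SE 0.20) changed in the authors' deposited table, and GstD3 (0.62, implied SE 0.24) did not. Of 16 antioxidant genes the peroxiredoxin Prx2540-1 changed, with 0.93 (implied SE 0.25) in the authors' deposited table; its paralog Prx2540-2 had 0.68 (implied SE 0.30) and may share its reads. The heat shock genes Hsp23 (-0.84, implied SE 0.26) and Hsp68 (-0.90, implied SE 0.29) were the 2 changed of 17 in the authors' deposited table, and 0 of 10 genes of the unfolded protein response changed or had an unadjusted p under 0.05.

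**Figure D2:**
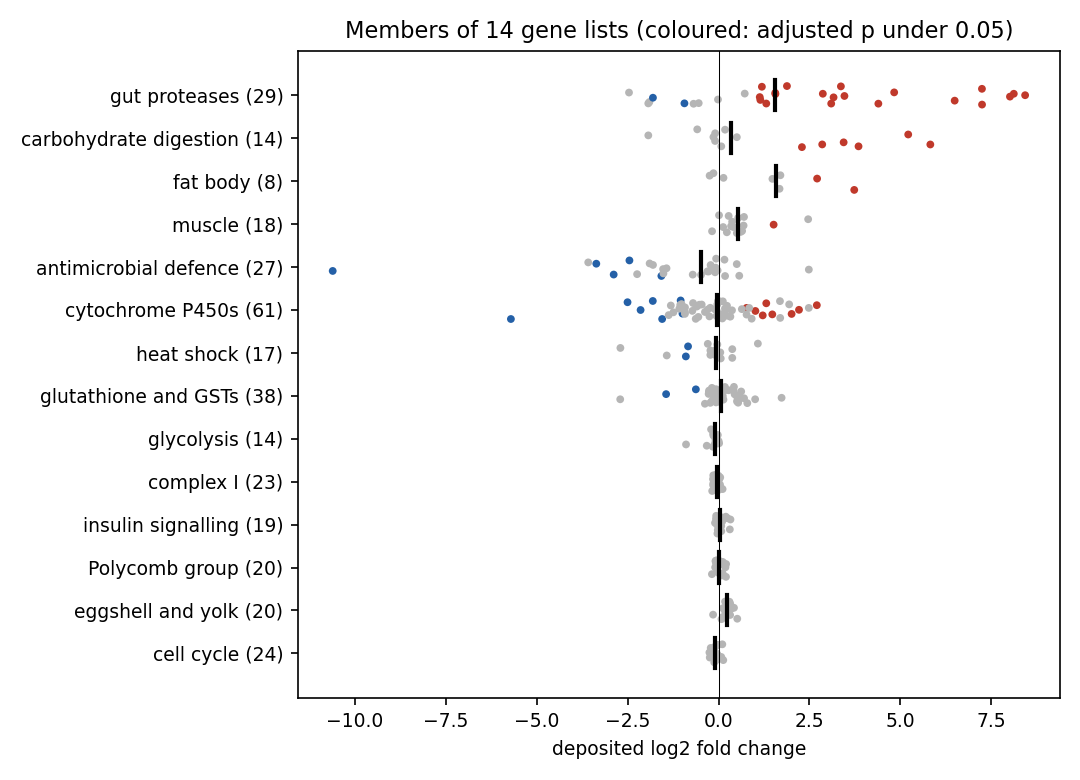
Deposited log2 fold change (horizontal axis) of each member of 14 gene lists (vertical axis, number of measured members in brackets). Coloured points have an adjusted p under 0.05 in the authors' deposited table and black bars are list medians; gut proteases spread to 8.43, while complex I, insulin signalling and cell cycle genes lie close to 0.

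Respiration differed little. Of 140 different genes of complex I, complexes II to V, the TCA cycle and the mitochondrial ribosome, 0 passed the edgeR threshold and 0 had an unadjusted p under 0.05, and their log2 fold changes lay between -0.33 and 0.29 in the authors' deposited table. For comparison, 234 of all 6398 genes of 16 CPM or more had an unadjusted p under 0.05 in the edgeR test. The median implied SE was 0.33 for complex I and 0.21 for the TCA cycle. A call took several times the implied SE. In the edgeR test Hsp68 passed at -0.90 (implied SE 0.29, adjusted p 0.0446), and the muscle gene sls did not at 0.69 (implied SE 0.24, adjusted p 0.0860). Differences of several times these median SEs in a single gene could therefore go uncalled. Succinate dehydrogenase subunit SdhB had -0.21 (implied SE 0.23) and the complex I subunit ND75 had -0.10 (implied SE 0.21) in the authors' deposited table. Of 92 cytosolic ribosomal protein genes 0 passed, with 1 at an unadjusted p under 0.05 in the edgeR test, the scarce RpS10a. No gene of the mitochondrial genome was found in the table under the names listed.

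Sugar metabolism was also close to even, with 0 of 32 genes of glycolysis, the pentose phosphate pathway and sugar storage past the edgeR threshold and 2 at an unadjusted p under 0.05. These were Tps1, the trehalose synthase, with -0.70 (implied SE 0.24), which passed on the negative side adjusted over the list alone, and Hex-C, a hexokinase, with -0.89 (implied SE 0.35) in the authors' deposited table. By ranks the glycolysis list had an adjusted p of 0.0161 on the negative side, against 0.475 in the main cameraPR test, at a median of -0.09 in the authors' deposited table. In fat synthesis v(2)k05816 changed, with 1.25 (implied SE 0.32) in the authors' deposited table, and acetyl-CoA carboxylase (ACC, 0.45, implied SE 0.18) and the fatty acid synthase gene CG3523 (0.49, implied SE 0.20) did not; the list had a cameraPR adjusted p of 0.265, and 0.0176 by ranks. The lipocalins NLaz (1.07, implied SE 0.23) and GLaz (1.26, implied SE 0.33) and the sterol transporter gene Npc1b (-1.20, implied SE 0.32) were the 3 changed of 11 genes of lipid droplets and lipoproteins in the authors' deposited table. Of 14 fat breakdown genes and 14 genes of one-carbon and NAD metabolism, 0 changed and 0 had an unadjusted p under 0.05 in the edgeR test.

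Chromatin regulators showed no call: 0 of 33 Polycomb and Trithorax group genes passed the edgeR threshold, and 1, the histone methyltransferase gene trx, had an unadjusted p under 0.05, with 0.40 (implied SE 0.19) in the authors' deposited table. Of 8 Hox genes, which Polycomb proteins are known to repress, abd-A changed with -1.08 (implied SE 0.35) at 68.3 CPM, and Abd-B had -2.38 (implied SE 0.91) with an adjusted p of 0.147 in the authors' deposited table. Among 18 early patterning genes odd (2.27, implied SE 0.56) and Sry-alpha (0.96, implied SE 0.24) changed in the authors' deposited table, and 6 of the 18 had no read in the compared libraries. Of 22 ecdysone pathway genes the synthesis genes nvd (1.10, implied SE 0.28) and sro (-1.67, implied SE 0.31) changed in the authors' deposited table. Adjusted over the list alone there were 7 on the positive and 1 on the negative side, and the list had a cameraPR adjusted p of 0.127, and 0.0199 by ranks.

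Genes of the cuticle-forming epidermis were nearly silent, and genes of the ovary and the early egg were abundant over the libraries of the fit. The 74 cuticle protein, 15 Tweedle and 18 Osiris genes, which serve the cuticle, had median averages of 0.0994, 0.0812 and 0.103 CPM in the authors' deposited table. For the 6 compared libraries an upper limit was set, at 0.0160 CPM for genes with no read in them (38 of the 107) and otherwise by giving them every read of the fit. The median upper limit over the 107 genes was 0.0161 CPM, and 1 gene, Osi19, could exceed 10 CPM. Of 18 muscle genes 15 had a lower limit of 10 or more reads per compared library, and of 18 neuron genes 7 had, while 3 neuron genes had no read there. The median upper limits of these lists were 4.35 and 1.01 CPM, and the highest were 979 CPM for Tm1 and 295 CPM for unc-13. The 20 eggshell and yolk genes had a median average of 921 CPM, the 21 maternal and germline genes 158 CPM and the 24 cell cycle genes 317 CPM in the authors' deposited table. From the size of the test statistic, each of the 20 eggshell and yolk genes had at least 1 read per compared library (median of the lower limits 11.3 reads). None of these 65 genes passed the edgeR threshold and 0 had an unadjusted p under 0.05; the eggshell and yolk median was 0.23 and the cell cycle median -0.10 in the authors' deposited table, and by ranks both lists had an adjusted p of 6.60e-03, on opposite sides.

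**Figure D3:**
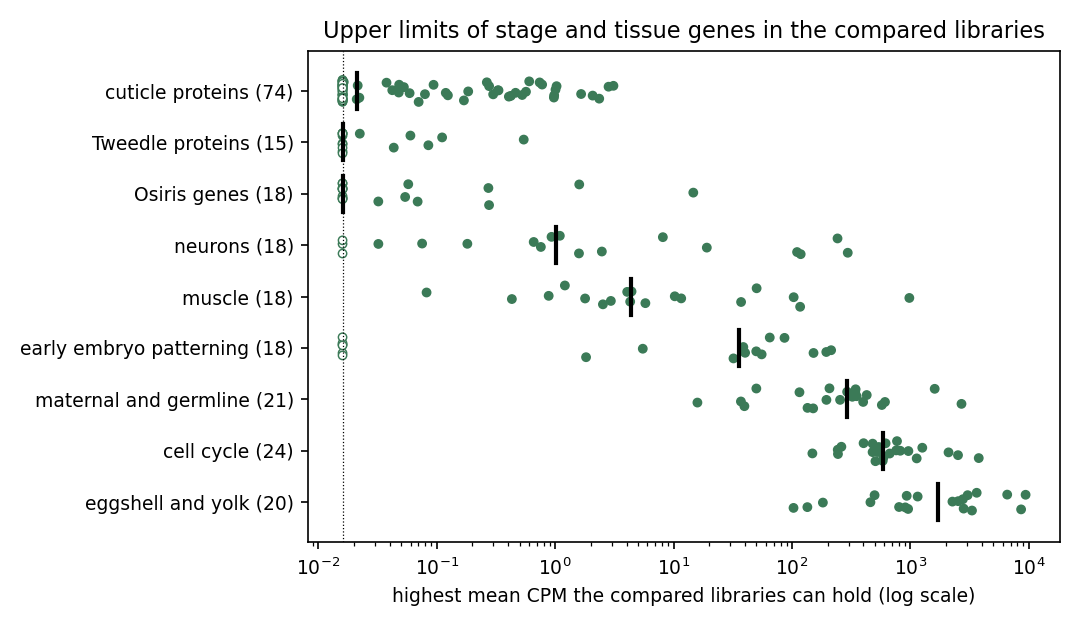
Highest mean CPM that the 6 compared libraries can hold (horizontal axis, log scale) for each member of 9 gene lists (vertical axis, number of members in brackets), with medians as black bars. Open symbols at the dotted line are genes with no read in these libraries, drawn at the limit of 0.0160 CPM; cuticle, Tweedle and Osiris genes lie far to the left of eggshell and yolk genes.

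In the cuticle list Cpr49Ae changed with -2.37 (implied SE 0.46), and 2 scarcer genes, Cpr47Ef and Cpr49Ab, also passed on the negative side in the authors' deposited table; by ranks the list had an adjusted p of 0.0258, against 0.195 in the main cameraPR test. Osi2 was the changed Osiris gene, with 1.70 (implied SE 0.32) in the authors' deposited table. Of 19 chitin and tracheal genes, Cht6 (1.26, implied SE 0.26), Idgf2 (0.64, implied SE 0.20) and pio (-1.20, implied SE 0.36) changed in the authors' deposited table. In the nervous system list, the calcium channel gene cac (0.68, implied SE 0.22) and the vesicular monoamine transporter gene Vmat (-1.40, implied SE 0.34) were the 2 changed of 18 in the authors' deposited table, with an adjusted p for the list of 0.305 by cameraPR and 0.0275 by ranks. Of 12 blood cell genes Pxn changed, with 1.64 (implied SE 0.53) in the authors' deposited table. No member changed among 8 glial, 11 photoreceptor, 15 Tweedle, 8 accessory gland and 46 replication histone genes in the edgeR test, where 1, 2, 1, 0 and 0 had an unadjusted p under 0.05; the histone list passed with the log2 fold change as the statistic (adjusted p 0.0194) and not in the main cameraPR test (adjusted p 0.840).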

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

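All tests of this part were chosen after the values were seen. The authors' deposited table holds a signal in libraries that the comparison does not use: 6 of the 12 libraries of the fit. In the authors' deposited table, 87 genes average 1 CPM or more over the fit with no read in the 6 compared libraries, so their reads came from the other 6. Mean levels there were 126 CPM for slp2, 113 CPM for sna, 113 CPM for CG34025, 109 CPM for CG31002 and 98.5 CPM for wor, against a limit of 0.0160 CPM in the compared libraries. The genes slp2, sna and wor encode transcription factors that act in the embryo. What these 6 libraries are is not given in the sources used here, and they were not analysed further.

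A first pattern is that cuticle, Tweedle and Osiris genes, apart from Osi19, which could exceed 10 CPM, were near 0 in the compared libraries. Embryos of 16 to 20 h form cuticle, and the median upper limit of 0.0161 CPM over these genes argues against the labelled stage. Muscle and neuron genes do not bear on it as clearly. Their median upper limits were 4.35 and 1.01 CPM, and 3 of 18 neuron genes had no read in the compared libraries. The upper limits of 979 CPM for Tm1 and 295 CPM for unc-13 give these libraries every read of the fit and are not measured levels. Low depth is argued against by a mean library size of 29.0 in units of 1000000 reads. What the compared libraries may hold in place of the labelled stage, such as RNA of egg chambers or of another stage, stays open. Of 18 early patterning genes 6 had no read in them, and 3 had a lower limit of 10 or more reads per library. The genes slp2, sna and wor had no read in them. Of 9 genes of the spermathecae, organs of adult females, 8 changed on the negative side, so that side held reads of them. Those 9 were gathered after the called genes were seen, and which source would give all of these was not tested. For 100% of the 20 eggshell and yolk genes the lower limit was 1 read or more per compared library. So low a bar does not tell egg chambers from traces: the median lower limit was 11.3 reads for these genes and 16.1 for muscle genes. Whether the table compares other libraries than its name says was not tested, and no biological explanation from the 2 groups was tested.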

How the results depend on the processing

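Of the counts and lists recomputed, 17 of 21 values of the main results stayed on their side or within 1.5 times. Requiring an average of 1 CPM leaves 344 genes, 209 positive and 135 negative, because 8732 genes are tested. The rank-based cameraPR passes 10 lists in place of 5; it adds glycolysis, fat synthesis, cuticle, ecdysone, eggshell, cell cycle and neuron genes and loses carbohydrate digestion and fat body, and the cause was not tested. An adjusted p under 0.01 leaves 490 genes and a 2-fold minimum 569. A correlation of 0.05 and the log2 fold change as the statistic each pass 5 lists. Added after the data were seen, the lists at 1 CPM or more pass 4 of 35, genes with a read in the compared libraries give 689 calls and 1 gene per group of equal values, after rounding, gives 662. The added filters leave each named gene's fold as it is and change only the adjustment; 1 named gene, Send2, crossed the threshold under them. No called list turned its direction.

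No paired analysis was possible because the authors' deposited table holds no values per sample. For the same reason other normalizations, count filters, the replicate block, leaving out each sample, other count tests, fry, an estimated correlation, the pseudocount and other splits of the samples were not run, so no count of regroupings of the 3 against 3 samples can be given. The p-values come from a fit of 12 libraries. Genes of 16 CPM or more had a median implied SE of 0.23, which holds the spread between libraries as well as counting error. Depth limits a gene with no read in the compared libraries to 0.0160 CPM.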

Other observations

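All tests and marker lists of this part were put together after the called genes were seen. Beside the serine proteases, 18 of 29 other midgut genes (lysozymes, lipases, amylases and others, 10 of them in the fixed lists) changed on the positive side and 2 on the negative side in the authors' deposited table. Levels here are averages over the 12 libraries of the fit, so they give no order within the compared libraries. The aspartic protease gene Bace had a log2 fold change of 5.40 (implied SE 0.31) at 8.69 CPM, and the lipase gene mag had 3.08 (implied SE 0.33) in the authors' deposited table. Of 21 genes of the Malpighian tubules 13 changed on the negative side and 0 on the positive side, among them Oatp58Dc at 80.2 CPM and the vitamin transporter gene Smvt, with -2.22 (implied SE 0.37) at 47.8 CPM, in the authors' deposited table. The other tubule genes with an average of 16 CPM or more did not pass. These were ZnT35C (-0.01 at 40.2 CPM), Picot (0.09 at 32.8 CPM), Irk1 (0.50 at 24.8 CPM) and Irk3 (-0.58 at 17.7 CPM) in the authors' deposited table. Of 9 secreted proteases of the spermathecae, the sperm storage organs of adult females, 8 changed on the negative side in the authors' deposited table, among them CG31681 at 1.09 CPM.

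Among genes with an average of 16 CPM or more, Scgdelta, a sarcoglycan gene, had a log2 fold change of 4.95 (implied SE 0.48) at 83.6 CPM and Jon65Aiv had 3.36 (implied SE 0.24) at 30.5 CPM in the authors' deposited table. On the negative side CG43163 had -4.35 (implied SE 0.29) at 48.4 CPM, CG8964 had -1.96 (implied SE 0.37) and CG43355 had -1.80 (implied SE 0.55) at 576 CPM in the authors' deposited table.

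A second pattern is the set of digestive genes on the positive side. Reads shared between near-identical proteases are argued against as the whole cause by 6 maltase and amylase genes, of other families, on the same side. Unequal carry-over of midgut may account for the pattern and cannot be told apart from an effect of the maternal transgene, since both predict positive genes and the 2 sides stand for the 2 groups by the name of the table. Of the 14 maltase and amylase genes 42.9% changed on the positive side and 8 did not pass, and the midgut genes Npc1b (-1.20) and Npc2e (-1.57) changed on the negative side in the authors' deposited table.

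A further pattern is the tubule and spermathecal genes on the negative side. A lower share of the main tissue in 1 group would move markers of every other tissue alike. The median of the 43 genes of the fixed digestive lists minus that of the 30 tubule and spermathecal markers was 4.34 on the log2 scale. Floor-level genes were set at their bound, and the interquartile ranges lay apart (medians 1.56 and -2.78). This comparison cannot decide on that cause, because the 30 markers were gathered after the changed genes were seen. Of the 43 digestive genes 26 changed on the positive and 2 on the negative side, and of the 30 markers 0 changed on the positive side. Unequal carry-over of tubules and spermathecae may account for the pattern and cannot be told apart from a difference between the groups: 70.0% of the markers changed on the negative side, but they were gathered after the changed genes were seen, so this share decides nothing between them.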
